A study of Phalaenopsis aphrodite subsp. formosana with 2 samples.

How the data were processed

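RNA was sequenced from leaf tissue of a variegated Phalaenopsis aphrodite subsp. formosana, a moth orchid whose leaves in this mutant carry sectors of different colour. There were 2 libraries, 1 from a green sector and 1 from a yellow sector. Per the labels' protocols, plants were grown in sphagnum moss in a greenhouse, total RNA was extracted with Trizol and an RNeasy Mini column, and libraries were made with the TruSeq RNA kit v2. The labels do not say how many plants or leaves each library came from, or whether both sectors came from the same leaf.

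The authors deposited a table of FPKM (fragments per kilobase of transcript per 1000000 mapped fragments) with 1 column per sector, named in the file header. Per the submitters' processing notes, CASAVA 1.8.2, TopHat and Cufflinks were among the tools used. The versions of TopHat and Cufflinks, the assembler, the options and the total that served as denominator are not given in the sources used here. Each of the 16843 rows is a locus with an identifier and the name of a contig, per the file headers. The contig names hold the number of a locus of the assembly, called the contig number here, which is not the locus of a row. They also hold a transcript number, a transcript count, a confidence value and a length. The names take the place of chromosome names, so no chromosome, exon or UTR position is given for any locus. Of the 15271 contigs, 1536 carry more than 1 locus, so that a count of loci is not a count of genes. All columns of sample values were used, and 0 columns were left out.

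The file pairs 0 of the 16843 identifiers with a gene name. The 31 gene lists that had been fixed before the data were examined (photosystems, chlorophyll and carotenoid metabolism, plastid proteins, stress, hormones and markers of other cell types, among others) therefore had 0 lists with a matched member, and no list median was computed. The planned comparison of each list of at least 5 members with 10000 random lists was not run. By the rule fixed at the same time for a table without gene names, at most 2 identifiers with the highest and 2 with the lowest log2 ratio are printed. Other loci are described by contig length and were chosen after their values were seen.

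From the deposited values, the ratio of the sectors was computed per locus as log2((yellow FPKM + 1) / (green FPKM + 1)). The pseudocount of 1 understates the change of low loci. A locus counted as measured where FPKM was at least 1 in at least 1 sector, which left out 35 loci. A locus counted as higher or lower by size where the ratio reached 2-fold on this scale. With 1 library per sector there is no spread between replicates, so no test between the sectors was made, no p-value is given, and the 2-fold rule is a rule of size alone. The size rule was tested on simulated data for the 11434 loci with 5 to 5000 FPKM in green, with Poisson noise at an assumed depth at which 1 fragment is worth 0.1 FPKM on a contig of 1000 bases. It returned 100.0% of 50 loci raised 3-fold and 97.7% of 44 loci lowered 3-fold. Loci below 5 FPKM were left out of the simulation, so it does not show how often counting noise alone passes 2-fold there or at the true depth, which is unknown. The value of 1 fragment was scaled by full contig length. If shorter lengths were used for the deposited FPKM on short contigs, noise there was understated.

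No fragment counts or library totals were used here, since the table holds none, so the depth of each library is unknown. Partial information was recovered from the low values. Where fragments are counted whole, FPKM is a whole number of fragments times a value per fragment that depends on length. This cannot hold for every locus. XLOC_000986, on a contig of 773 bases, was listed at 5.36e-05 FPKM in green, too little for a whole fragment at any usual depth. Loci with the same green FPKM and the same length share that value, and their yellow FPKM should then stand in the ratio of their fragment numbers. The length Cufflinks used for each locus is not in the table, so contig length was taken in its place, and 277 of the 317 groups with the same green FPKM joined contigs of different length. There the ratio of yellow FPKM can still be one of whole numbers, but the numbers need not be fragments, so fragment numbers were taken only from groups on contigs of equal length. In each group only the lowest distinct yellow FPKM and the next higher one were compared. Ratios were tested with whole numbers up to 30 and a relative tolerance of 2e-05. In simulated data for 9000 loci, 98.6% of 501 groups of equal length and 81.9% of 816 groups of different length had such ratios. The smallest whole numbers were at or below the true fragment numbers in 100.0% of the former with a ratio and in 46.9% of the latter with a ratio.

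The alternatives fixed before the data were examined were pseudocounts of 0.1 and 10, no filter and a minimum of 10 FPKM, centring on the median, rescaling each sector to a sum of 1000000, leaving the 100 most abundant loci out of that total, and a 4-fold rule. Alternatives that need interval bounds or a status per value could not be run. Counts were taken as moved beyond 1.5 times, percentages beyond 10 points, correlations beyond 0.05 and medians beyond 0.1. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9.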

Results

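The transcriptomes of a green and a yellow leaf sector of the variegated orchid were compared, with 1 library per sector, to examine how sectors of different colour differ in gene expression. FPKM values were available for 16843 loci on 15271 contigs with a median length of 1518 bases (116 to 16771 bases). The median FPKM was 8.47 in the green sector (quartiles 4.08 and 19.5) and 8.92 in the yellow sector (quartiles 4.63 and 20.01). The identifiers are paired with no gene names, so that the results are given by locus, contig length and abundance.

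The sequencing depth of neither library is known, but the low FPKM values carried traces of whole fragments. In each of 317 groups of loci with an identical green FPKM and different yellow FPKM, the lowest yellow value was compared with the next. In 179 groups (56.5%) these values stood in a ratio of whole numbers up to 30, within a relative tolerance of 2e-05. The same was true of 126 of 16401 pairs (0.768%) of loci that were neighbours in green FPKM without being identical. The loci of a group lay on contigs of equal length in 40 groups, of which 31 (77.5%) had such a ratio, and on contigs of different length in 277 groups, of which 148 (53.4%) did. For equal length the simulated data, which held whole fragment numbers only, had given a higher share, 98.6%. In the 31 groups the smallest whole numbers that fitted the compared values were a median of 11 in yellow. The median of those yellow values was 5.08 FPKM, on contigs with a median length of 420 bases. These are lower limits on the fragments if equal contigs gave equal effective lengths and if fragments were counted whole. Since whole numbers only up to 30 were tried, only loci with few fragments could be resolved. In groups on contigs of different length the numbers need not be fragments.

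The sectors were similar for most loci. Of the 16808 loci with at least 1 FPKM in at least 1 sector, 13832 (82.3%) lay within 2-fold. The median log2 ratio of yellow to green was 0.01, with quartiles at -0.38 and 0.45. Across these loci Pearson's r of log2(FPKM + 1) was 0.86 and Spearman's rho was 0.80. These correlations are across loci, which are not independent replicates.

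At the deposited scaling, more loci were higher than lower in the yellow sector by the size rule. At least 2-fold higher values were found for 1932 loci (11.5%) and at least 2-fold lower values for 1044 loci (6.21%), so that 64.9% of the loci past 2-fold were higher in yellow. Past 4-fold, 700 loci were higher and 165 lower (80.9% higher). Past 8-fold, 147 were higher and 36 lower (80.3% higher). The loci higher in yellow had a median FPKM of 2.24 in green and 11.4 in yellow. The loci lower in yellow had a median FPKM of 15.6 in green and 4.72 in yellow. Without replicates it cannot be said how many of these differences exceed the variation between leaves or between sectors of one colour. The split varied with scaling. After centring on the median locus, 1920 loci were higher and 1061 lower (64.4% higher). With yellow FPKM divided by 1.18, the ratio of the sector totals without the single most abundant locus, 1557 loci were higher and 1630 lower (48.9% higher). The median log2 ratio was then -0.20, and the split was close to even. With the ratio of the totals without the 100 most abundant loci, 1859 were higher and 1136 lower (62.1%). Rescaling each sector to a sum of 1000000 also changes the weight of the pseudocount. With the 100 most abundant loci left out of that sum, which raised values 2.71-fold in green and 2.61-fold in yellow, 2039 were higher and 1362 lower (59.95%). With only the most abundant locus left out of it, which lowered values 3.43-fold in green and 4.03-fold in yellow, 1057 were higher and 948 lower (52.7%). With that locus in the sum, of which it holds nearly all, the figure was 2.39%, a value set by that locus and uninformative on the others.

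**Figure D1:**
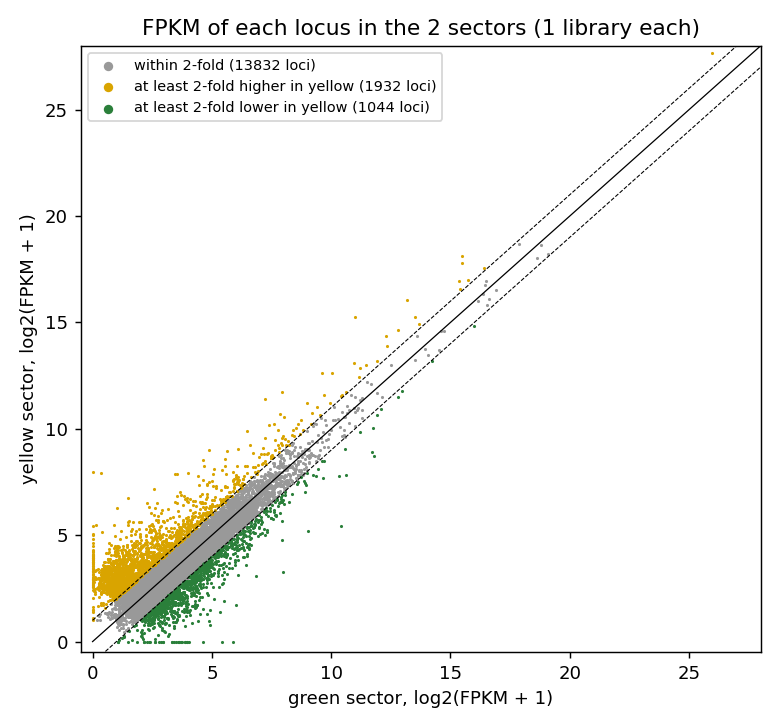
FPKM of each of the 16808 measured loci in the green (x axis) and yellow (y axis) sector, both as log2(FPKM + 1); 1 point is 1 locus, the solid line marks equal values and the dashed lines mark 2-fold differences. Of these loci, 1932 lie at or above the upper dashed line and 1044 at or below the lower one, and the single point at the far upper right is the locus listed at 64900000 FPKM in green.

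The locus with the highest ratio was XLOC_001670, on a contig of 897 bases, which was listed at 0 in green and at 249 FPKM in yellow. The other locus on that contig differed less, with 3.77 FPKM in green and 13.3 FPKM in yellow, a 3.54-fold higher value. The second was XLOC_009049, on a contig of 2213 bases, with 0.296 FPKM in green and 245 FPKM in yellow. The other locus on its contig had 1.06 FPKM in green and 75.6 FPKM in yellow, a 71.6-fold higher value. At the other end, XLOC_013867, on a contig of 2468 bases, had 58.1 FPKM in green and was listed at 0 in yellow. The other locus on its contig had 3.67 FPKM in green and 1.90 FPKM in yellow, within 2-fold. XLOC_004500, on a contig of 194 bases, had 41.5 FPKM in green and was listed at 0 in yellow. No fold is given against a value of 0. In all, 57 loci were listed at 0 in green alone, 35 in yellow alone and 1 in both.

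Among loci on contigs of at least 500 bases with at least 1 FPKM in both sectors, the lowest ratio belonged to a locus on a contig of 1699 bases. It had 1349 FPKM in green and 42.0 FPKM in yellow, which is 32.1-fold lower. A locus on a contig of 581 bases had 254 FPKM in green and 8.81 FPKM in yellow, 28.8-fold lower. One on a contig of 1218 bases had 525 FPKM in green and 36.3 FPKM in yellow, 14.5-fold lower. In the opposite direction, a locus on a contig of 1007 bases had 4.99 FPKM in green and 143 FPKM in yellow, 28.7-fold higher. A locus on a contig of 705 bases had 10.1 FPKM in green and 237 FPKM in yellow, 23.5-fold higher.

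Differences past 2-fold were more frequent on short contigs, in both directions. On contigs of up to 300 bases, 27.5% of 949 loci were higher and 17.6% lower in yellow. On contigs of 501 to 1000 bases, 18.1% of 2857 loci were higher and 7.46% lower. On contigs of 2001 to 3000 bases, 5.56% of 3419 loci were higher and 3.77% lower. On contigs above 3000 bases, 5.10% of 2275 loci were higher and 2.59% lower. At the deposited scaling more loci were higher than lower in yellow in each of the 7 length classes, with 58.5% to 70.8% of those past 2-fold being higher.

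**Figure D2:**
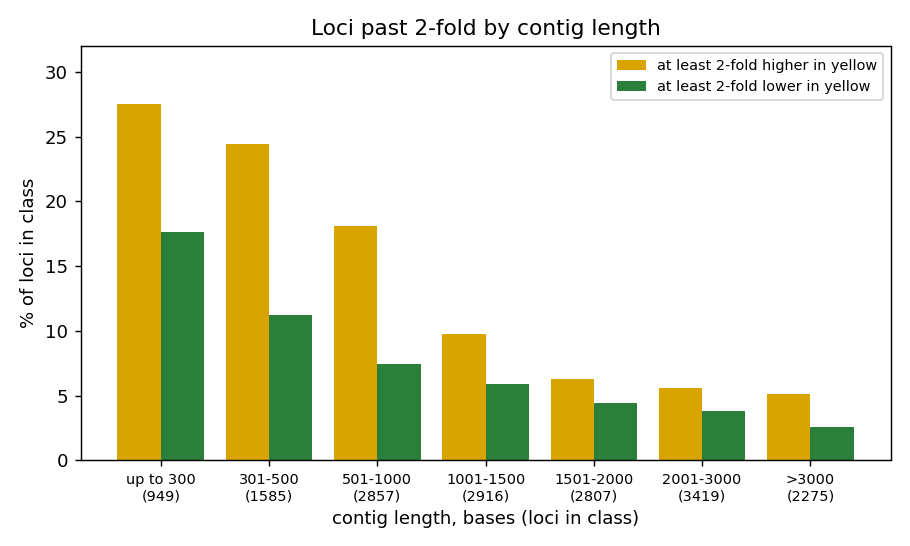
Percentage of loci in each contig length class (x axis, bases, with the number of loci in brackets) that were at least 2-fold higher (yellow bars) or lower (green bars) in the yellow sector. Both percentages fall from the shortest class, at 27.5% and 17.6%, to the class above 3000 bases, at 5.10% and 2.59%.

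At the deposited scaling the excess of loci higher in yellow also varied with abundance, taken as the geometric mean of FPKM + 1 over the sectors, less 1. At a mean of up to 3 FPKM, 504 of 2109 loci were higher and 144 lower in yellow (77.8% of those past 2-fold higher). Between 15 and 31 FPKM, 181 of 2675 loci were higher and 167 lower (52.0%). Above 127 FPKM, 93 of 578 loci were higher and 47 lower (66.4%). Of the 112 loci with at least 1000 FPKM in either sector, 41 were higher and 14 lower in yellow, and the median contig length of these loci was 322 bases.

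Summed FPKM was concentrated in a few loci. A locus on a contig of 250 bases was listed at 64900000 FPKM in green and 210000000 FPKM in yellow, which was 116 and 501 times the next highest value of each sector. It held 94.98% of the green and 98.1% of the yellow total. With that locus left out, the 10 most abundant loci held 65.7% of the green and 61.6% of the yellow total, and the remaining total was 1.18 times as large in yellow as in green. FPKM divides by length, so these shares are not shares of fragments.

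Loci that share a contig gave an internal comparison, although they are not replicates. On the 1472 contigs with exactly 2 measured loci, the log2 ratios of the pair correlated at 0.58, against at most 0.08 in 1000 shuffles of the pairing. Partners were shuffled over all contigs, without matching contig number, length or abundance. The shuffles therefore do not show whether the correlation exceeds what these shared traits give. The median difference within a pair was 0.33 on the log2 scale, or 1.25-fold, and in 12.4% of pairs the ratios were at least 1 log2 unit apart. Of 308 contigs with at least 1 locus past 2-fold, 59 had both loci higher in yellow, 33 had both lower, 1 had the loci in opposite directions and 215 had 1 locus past 2-fold.

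The ratio between the sectors also varied with the contig's number in the assembly. For the 9150 loci on contigs numbered up to 8000, the median log2 ratio was -0.04, with 496 loci at least 2-fold higher and 481 lower in yellow (50.8% of those past 2-fold higher). For contigs 10001 to 11000, 11001 to 12000 and 12001 to 13000 the share higher was 68.5%, 67.9% and 80.4%, and the median log2 ratio was 0.05, 0.06 and 0.18. For the 895 loci on contigs numbered from 13000 up to 14000 the median was 1.19 (quartiles 0.13 and 2.16), with 475 loci at least 2-fold higher and 51 lower in yellow. The median FPKM of these loci was 2.26 in green and 5.79 in yellow. For the 1666 loci on higher-numbered contigs the median log2 ratio was -0.03, with 286 loci higher and 224 lower (56.1%). These ranges of numbers were chosen after their values were seen. Contig length changed along with contig number, from a median of 2246 bases for contigs 1 to 1000 to 377 bases for contigs 13751 to 14000. In the ranges from contig 14251 on, contigs were about as short, with medians of 359 to 442.5 bases. The median log2 ratio there was -0.14 to 0.16, at a higher median green FPKM of 11.9 to 43.2. From contigs 12001 to 13000 to contigs 13751 to 14000, the median FPKM fell from 3.32 to 1.13 in green and rose from 4.33 to 7.75 in yellow.

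**Figure D3:**
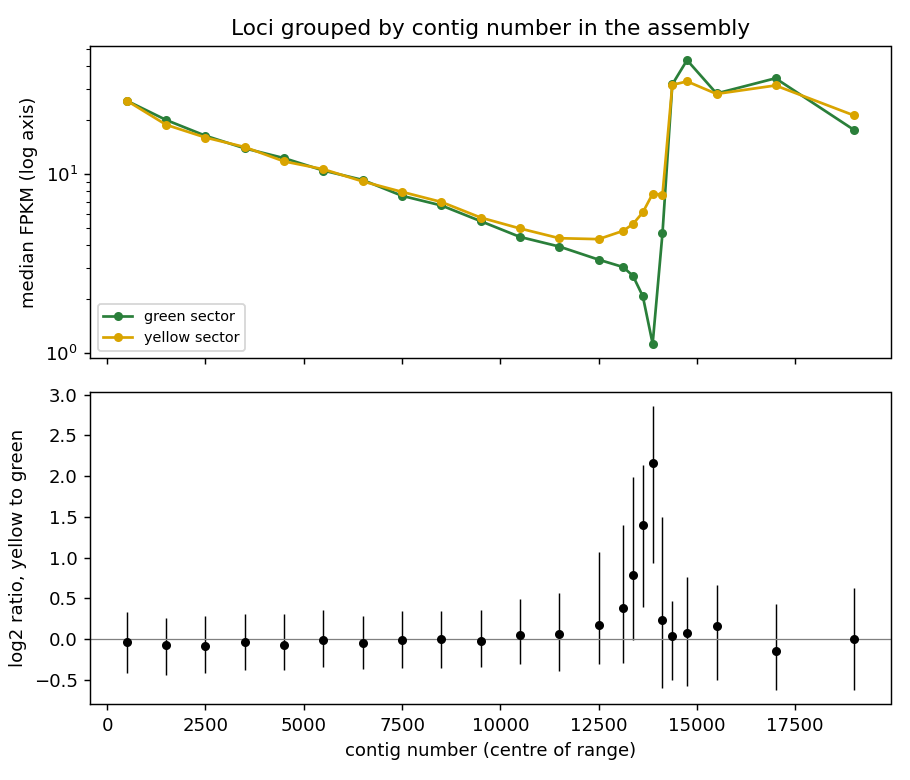
Loci grouped by the number of their contig in the assembly (x axis, centre of each range): the upper panel gives the median FPKM in the green and yellow sectors on a log axis, and the lower panel the median log2 ratio of yellow to green, with bars from the lower to the upper quartile. The ratio is 0.06 for contigs 11001 to 12000, reaches a median of 2.16 for contigs 13751 to 14000 and is 0.07 for contigs 14501 to 15000.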

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

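Of the 46 values recomputed under alternatives, 27 stayed within the limits set for them, 17 moved and 2 reversed. Some of the 27 could hardly have moved. With a pseudocount of 1, a locus under 1 FPKM in both sectors cannot reach 2-fold, so dropping the filter could not change the counts. Centring shifted the log2 ratios by only 0.008. The alternatives on contig length, on contig numbers, on leaving out the single most abundant locus and on dividing yellow FPKM by a ratio of totals were added after seeing the data. A pseudocount of 10 left 566 loci higher and 282 lower in yellow, a minimum of 10 FPKM left 1081 and 684, and a 4-fold rule left 700 and 165 (80.9% higher). These settings ask for more by construction. Contigs of at least 1000 bases gave 767 and 486. Rescaling to a sum of 1000000 per sector gave 11 loci higher and 449 lower, which reversed the split to 2.39% higher. That total is almost wholly 1 locus, and it shrinks all other values towards the pseudocount. With that locus left out of the sum, 1057 loci were higher and 948 lower (52.7%), but values were still lowered 3.43-fold in green and 4.03-fold in yellow against the pseudocount. Dividing yellow FPKM by the ratio of the same totals alone left 1557 loci higher and 1630 lower, a share of 48.9% higher. This share was counted as reversed, but it lay close to an even split. With the ratio of the totals without the 100 most abundant loci it was 62.1%. Without the most abundant locus the share of the 10 most abundant loci was 65.7% in green and 61.6% in yellow against 98.1% and 99.2% with it. Centring on the median (64.4%) and leaving the 100 most abundant loci out of the total (59.95%) stayed within the limits. Spearman's rho was 0.73 at a minimum of 10 FPKM. No alternative was possible for the gene lists, the interval bounds or the status per value, which need data not used here. No paired analysis was possible because there is 1 library per sector, and leaving out a replicate was not possible for the same reason. What depth limits is known only in part, since whole fragments could be traced for few loci and only where fragments were few.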

Other observations

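The test on long contigs, the centring and the totals without the 100 most abundant loci were set out before their values were seen, and the other tests of this part were chosen after. Intervals treat loci as independent and cover no variation between leaves.

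More loci were at least 2-fold higher than lower in yellow (64.9% of those past 2-fold). Short contigs are argued against as the whole source, since 60.6% were higher on contigs of at least 1500 bases (exact binomial 95% interval 57.1 to 64.0). High contig numbers stay open as the source. On contigs numbered up to 8000, 50.8% (47.6 to 53.9) were higher, with no clear excess. The share was 70.1% above contig 8000 up to 13000 and 90.3% from 13000 to 14000. Above contig 14000 it was 56.1% (51.6 to 60.4). With contigs numbered 13000 to 14000 left out, 59.5% were higher. Contig number goes with length and with green FPKM. Scaling stays open for the 2-fold excess: centring on the median locus gave 64.4% and totals without the 100 most abundant loci 59.95% (62.1% by the ratio of those totals alone), but dividing yellow FPKM by 1.18, the ratio of the totals without the extreme locus, gave 48.9% higher (47.1 to 50.6), with the median log2 ratio at -0.20 and with 10 loci holding 65.7% of that green and 61.6% of that yellow total. Scaling of that size is argued against for the 4-fold excess, where 70.1% (66.7 to 73.3) were higher. The other explanations were not tested for the 4-fold excess. It was not recomputed without the contigs numbered 13000 to 14000, and the median log2 ratio was 2.16 for contigs 13751 to 14000. Few fragments at low FPKM stay open, with 55.4% (51.9 to 58.9) higher among loci with a geometric mean above 15 FPKM. That interval lies above an even split but includes the limit of 55% set for the test. Above 127 FPKM the share was 66.4% (58.0 to 74.2). That value cannot decide, because on a short contig a high FPKM need not mean many fragments. The loci with at least 1000 FPKM lay on contigs with a median length of 322 bases. On contigs of at least 1000 bases, 480 loci with at least 10 FPKM in at least 1 sector were higher and 344 lower (58.3% higher). No interval was computed for that share, so it does not decide. A difference between the sectors themselves is open and untested.

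Loci on contigs numbered 13000 to 14000 had a median log2 ratio of 1.19, and a candidate explanation is that contig numbers follow abundance in the green library, for example if an assembler numbered contigs as they were first met in reads of which the green ones came first. Over all contigs the partial Spearman rho of contig number with green FPKM given yellow FPKM was -0.252, and with yellow FPKM given green FPKM it was 0.004 (-0.30 and -0.08 up to contig 13000). This stays open, because above contig 14000 the same values were 0.03 and -0.07. Median green FPKM was 4.66 for contigs 14001 to 14250 and 31.6 for contigs 14251 to 14500, against 25.6 for contigs 1 to 1000. The last 2 ranges had median contig lengths of 389 and 2246 bases, so their FPKM does not compare numbers of fragments and does not decide. Of the loci above contig 14000, 90.0% lay on contigs whose name gives a transcript count of 1, against 6.41% up to contig 14000. There was no break at contig 14000 itself. The share was 55.3% for contigs 13751 to 14000, 62.1% for contigs 14001 to 14250 and 48.6% for contigs 14251 to 14500. It was 100% only from contig 15001 on. Few fragments cannot be told apart from numbering by green abundance either. For contigs numbered 13000 to 14000, the 81 loci on contigs of at least 1000 bases had a median log2 ratio of 1.19 (bootstrap 95% interval 0.61 to 1.73). The 25 on contigs of at least 1500 bases had 0.51 (0.08 to 0.87), and that interval includes the limit of 0.3 set for the test. A difference between the sectors themselves is also open and untested.

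The locus listed at 64900000 FPKM in green and 210000000 FPKM in yellow may reflect an effective length close to 0. If FPKM was taken per library total, then even if every fragment of a library came from it these values would allow an effective length of at most 15.4 bases in green and 4.76 bases in yellow, on a contig of 250 bases. Whether the effective length differed between the sectors was not tested, so its 3.24-fold higher value in yellow is left as a value. No biological explanation was tested for it.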
